A study of Mus musculus with 12 samples.

How the data were processed

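RNA of 30 eggs per sample was isolated, amplified and labelled by the Affymetrix small-sample protocol and hybridised to mouse arrays, per the labels' protocols. The deposited table held 1 intensity per probe set and array for 12 arrays, on a linear scale from a minimum of 4.9. The authors made these intensity values with GCRMA, which corrects background by probe sequence, normalizes between arrays and summarises probes, per the submitters' processing notes. The GCRMA version is not given in the sources used here. GCRMA pulls weak signals to a common floor, and 55.6% of all values were at or under 5 units, so folds of dim probe sets depend on that floor. Normalization between arrays makes each value relative to the other transcripts of its array. A change in total mRNA per egg is therefore not visible in these values. No detection calls were used. The arrays' number, not a read depth, limits precision.

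Values were taken to log2. Of 45101 probe sets, 64 controls were left out, and of the remaining 45037 those with log2 above 5 (intensity above 32) in at least 3 of the 12 arrays, whatever their groups, were tested. This left 11593. Probe sets were named from the platform annotation. On the whole array 34945 probe sets had 1 gene symbol, 932 had several and 9160 were unnamed, and among those tested the numbers were 10699, 334 and 560. Symbols were looked up by Entrez gene number in the RefSeq gene table of GRCm38.p6, where 34754 of 34958 matched and 0 changed. No gene was named from a probe set with several symbols, and no genome sequence was used, so no coordinates are given.

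Groups were compared with the moderated test of limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) on group means over all 12 arrays, with 8 residual and 2.97 prior degrees of freedom. Contrasts covered each single knockdown and the double knockdown against control, the double against each single knockdown, the single knockdowns against each other, and the interaction, the change by both siRNAs minus the sum of the single changes. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets of a comparison and a threshold of 0.05. Errors of log2 changes are standard errors of the fit. The quality and control probe sets were compared with exact permutation tests, where 3 arrays against 3 give 10 splits and no p under 0.1. Where the mean or median log2 value of the dimmer group was at or under 5, the fold is given as a bound, the mean log2 value of the brighter group minus the mean of the higher of 5 and the array's own log2 value, and the fitted change is not a bound. Such a bound allows for the floor only and not for the spread among replicates, so it is no confidence limit.

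Before the data were examined, 21 gene lists, the design, the alternatives and the rule for naming genes were fixed. Lists covered decapping and 5′-to-3′ decay, deadenylation, exosome and nonsense-mediated decay, translation control of maternal mRNA, small RNAs, growth-phase and maternal-effect genes, dormant maternal mRNAs, meiotic cell cycle, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, proteasome, histones, splicing, chromatin, zygotic genome activation, interferon response, p53 and stress, immediate-early genes, and markers of cumulus cells and of other ovarian cells. Each gene was represented by the tested probe set with the highest mean over the 12 arrays, which gave 6998 genes. Lists were tested with camera (correlation preset to 0.01), with camera under an estimated correlation and with fry, adjusted over the lists of a comparison. The naming rule took Dcp1a and Dcp2 and, from the double knockdown against control, the 12 genes with the largest rise and the 12 with the largest fall. From each single knockdown against control it took up to 8 each way, and from the other comparisons 5 each way. All had to pass the threshold, have exactly 1 symbol that was not of clone style and, outside the interaction, have groups that did not overlap. From each list up to 4 members past the threshold were named, or the pair with the smallest p where fewer than 2 passed. Clone-style symbols left 18 called probe sets of the double knockdown against control unnamed.

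The procedure was tested on simulated data for the double knockdown against control with 11593 probe sets. It recovered 28 of 100 probe sets changed 2-fold and 81 of 100 changed 4-fold, all in the right direction, with 9 false calls. Changes of 2-fold were thus often missed in the simulation. No probe sets beyond these were changed there, while 1011 were called in the data. Adjustment was therefore stricter in the simulation, and the share recovered in the data was not measured. Among lists, camera called the 1 list shifted by 0.5 and 0 of 18 others. The simulated genes varied independently of each other, so this does not test the preset correlation. In the data the estimated correlation was 0.15 for ribosomal proteins and 0.177 for oxidative phosphorylation.

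Alternatives were the replicate number as a block, each array left out in turn, no filter, a filter at log2 7, median centring, quantile normalization, cyclic loess, an intensity trend with a robust prior, array weights, only the arrays of the compared groups, leaving out probe sets that can match several transcripts, 16 added to each intensity, and folds of at least 1.5 or 2. Setting values under 32 to 32 and leaving out Dcp2 knockdown replicates 1 and 3 together were added after the data were seen.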

Results

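Messenger RNA was profiled on 12 Affymetrix arrays in CF1 mouse eggs arrested at metaphase of the second meiotic division. Full-grown oocytes had been injected with siRNA against Dcp1a, a cofactor of mRNA decapping, against Dcp2, the enzyme that removes the 5′ cap, against both, or with a control siRNA. They were then held in milrinone for 20 h and matured for 18 h. Each of the 4 groups had 3 independent biological replicates of 30 eggs, so the p-values of the limma tests measure the spread among such pools. The series asked how loss of the decapping factors during maturation changed the mRNA content of the egg. Full-grown oocytes are transcriptionally quiescent, so maturation runs on stored maternal mRNA, part of which is degraded by the egg stage. Values were relative within an array, so a change in the total amount of mRNA per egg was not measured. Replicates correlated at r between 0.938 and 0.967 across probe sets in the control group and between 0.991 and 0.992 in the Dcp1a knockdown. The ranges were 0.938 to 0.973 in the Dcp2 knockdown and 0.958 to 0.989 in the double knockdown. Arrays did not all correlate best within their own group. Control replicate 1 had r of 0.978 to 0.988 with the Dcp1a knockdown arrays, against 0.938 to 0.954 with the other control arrays. Dcp2 knockdown replicate 2 had r of 0.978 to 0.986 with the Dcp1a knockdown arrays, against 0.938 to 0.963 within its group.

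The brightest probe set of Dcp1a and that of Dcp2 read lower in every array that received the matching siRNA than in any control array. The brightest Dcp1a probe set had an intensity of 8632 ± 3553 in control eggs, 1011 ± 365 after Dcp1a siRNA and 791 ± 387 after both siRNAs (mean ± SD, n = 3 each). In eggs given only Dcp2 siRNA it was 8031 ± 1990. The residual level was 11.8% of control in the Dcp1a knockdown and 9.02% in the double knockdown, as ratios of geometric means. The corresponding log2 changes were -3.09 ± 0.42 (SE, adjusted p = 0.0319, limma) and -3.47 ± 0.42 (adjusted p = 0.000666, limma). A dimmer Dcp1a probe set was at least 1.25-fold lower in both groups (adjusted p = 0.00378 in the Dcp1a knockdown and 0.000126 in the double knockdown, limma). The remaining one varied widely among control arrays (1227 ± 1866, SD, n = 3) and passed in neither group. The call for Dcp1a in the single knockdown ended when any of 9 of the 12 arrays was left out, while its log2 change stayed between -3.39 and -2.74.

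Dcp2 mRNA was dim before treatment, with an intensity of 48.1 ± 29.2 in control eggs and 46.2 ± 12.6 after Dcp1a siRNA (SD, n = 3). It lay at the floor of the scale, 4.97 ± 0.06 and 4.93 ± 0.06, in the Dcp2 and double knockdowns. Against the floor of 32 units used throughout, Dcp2 was at least 1.35-fold lower than in control eggs in both groups. The adjusted p was 0.0152 in the Dcp2 knockdown and 0.000378 in the double knockdown (limma). With values under 32 set to 32 the Dcp2 calls were lost, with adjusted p of 0.508 and 0.38. The other Dcp2 probe set read 4.9 on all 12 arrays.

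**Figure D1:**
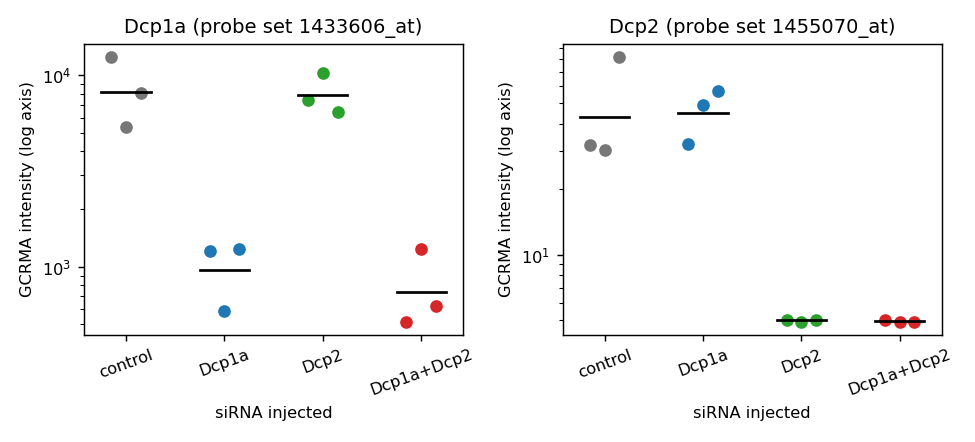
GCRMA intensity (log axis) of the Dcp1a and Dcp2 probe sets in each of the 12 arrays by siRNA injected, with bars at the geometric mean of 3 arrays. Dcp1a was at 9.02% of control in the double knockdown, and all Dcp2 values in the Dcp2 and double knockdowns were at or under 5, below the lowest control value of 30.4.

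Depletion of both factors together gave the broadest change. Of 11593 probe sets tested, 768 were higher and 243 lower in the double knockdown than in control eggs, corresponding to 583 and 215 genes (limma, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 the split was 1834 higher to 1394 lower. The median fold change of the called probe sets was 3 upward and 2.29 downward on the fitted scale, which overstates folds of probe sets near the floor. List genes were counted by their probe set with the highest mean. The called members of the lists for the cytosolic ribosome, the mitochondrial ribosome and the respiratory chain were mostly higher. Camera called these 3 lists higher with a preset correlation only, and gave adjusted p = 0.289, 0.36 and 0.36 with an estimated correlation. The directional test of fry called them higher, with adjusted p = 0.000768, 0.000768 and 0.00154. Of 40 cytosolic ribosomal protein genes tested, 17 rose and 0 fell, and 24 rose when adjusted over the list alone. The median log2 change of the list was 1.20, or 0.97 with values under 32 set to 32. The list passed camera with a preset correlation of 0.01 (adjusted p = 8.04e-11), and gave adjusted p = 0.289 with an estimated correlation. Rpl10a rose 3.42 ± 0.58 on the log2 scale (SE, adjusted p = 0.00494, limma). Rpl19 rose 3.30 ± 0.50, Rps4x 3.02 ± 0.69 and Rpl7a 2.81 ± 0.64 on the same scale. The average level of the list, relative to the mean of all 12 arrays, lay at 0.93 to 1.13 in the double knockdown and at -0.54 to 0.24 in the other 9 arrays, with control replicate 3 the highest of those.

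Among 67 genes of oxidative phosphorylation, 23 rose and 0 fell (28 and 0 adjusted over the list alone), with a median log2 change of 0.57 (0.51 with values under 32 set to 32; camera adjusted p = 5.33e-09, and adjusted p = 0.36 with an estimated correlation). Of the complex I subunits, Ndufs8 was at least 7.49-fold and Ndufa9 at least 6.63-fold higher, and Ndufs7 rose by 3.06 ± 0.58 (log2, SE, limma). Atp5g1, a subunit of the membrane ring of ATP synthase, was under 32 units on all control arrays and at least 3.38-fold higher in the double knockdown (adjusted p = 1.63e-05, limma). The 56 mitochondrial ribosomal protein genes had 13 that rose and 1 that fell, against 16 and 4 adjusted over the list alone, and a median of 0.28 (0.22 with values under 32 set to 32). Their camera adjusted p was 0.0148 with the preset and 0.36 with an estimated correlation, and 0.0892 without control replicate 1. Mrpl12 was at least 3.51-fold and Mrpl22 at least 8.14-fold higher, and Mrpl41 and Mrpl58 rose by 2.69 ± 0.39 and 1.87 ± 0.29 (log2, SE, limma). Other probe sets, chosen after their values were seen, were called lower for Mrps6 (-1.29 ± 0.31) and higher for Mrps24 (1.20 ± 0.33). The medians of these 3 lists kept their sign under median centring, quantile normalization and cyclic loess.

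**Figure D2:**
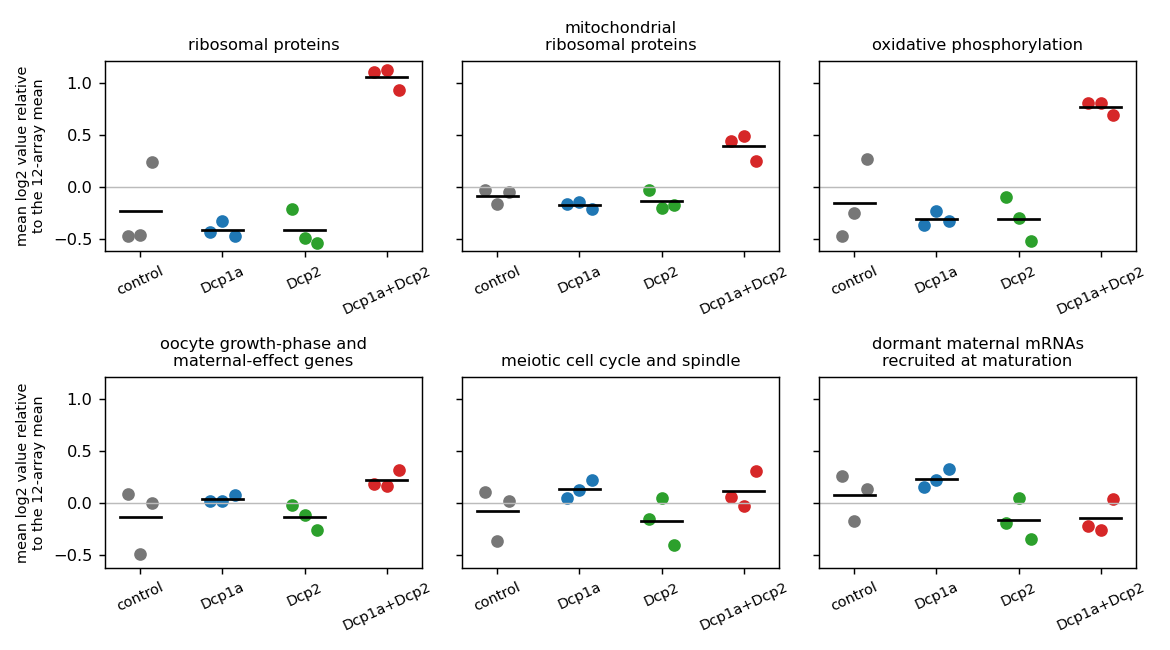
Mean log2 value of the members of 6 gene lists in each of the 12 arrays, relative to the mean of all arrays, by siRNA injected, with bars at the mean of 3 arrays. The ribosomal protein values of the double knockdown, 0.93 to 1.13, lie above all 9 other arrays, and the dormant maternal mRNAs overlap between groups.

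Several genes that define the oocyte also rose with both siRNAs. Of 59 growth-phase and maternal-effect genes 7 rose and 0 fell (8 and 0 adjusted over the list alone), although the list did not pass camera (adjusted p = 0.12, median log2 change 0.12). By other probe sets, chosen after their values were seen, Brwd1 of this list was called lower (-1.89 ± 0.23, adjusted p = 0.000735, limma). Smarca4 was called higher in the same way (1.24 ± 0.28, adjusted p = 0.0192, limma). Zp3 and Zp2, which encode proteins of the zona pellucida, rose by 2.14 ± 0.47 and 2.08 ± 0.42 (log2, SE; adjusted p = 0.0187 and 0.0122, limma). The gap junction gene Gja4 rose by 2.19 ± 0.53 and Zfp57, a zinc finger protein needed for imprints, by 1.55 ± 0.36. Among 60 meiotic cell cycle genes 3 rose and 1 fell, both overall and adjusted over the list alone (median 0.20, camera adjusted p = 0.375). The anaphase-promoting complex genes Anapc7 and Anapc2 rose by 2.17 ± 0.50 and 1.66 ± 0.18, its ubiquitin-conjugating enzyme Ube2c by 1.01 ± 0.25, and the kinetochore gene Ndc80 changed by -1.34 ± 0.28 (log2, SE, limma). The other probe set of Anapc7 had a change of -0.54, opposite in sign. Other probe sets, chosen after their values were seen, were called higher for Arpp19 (1.34 ± 0.30) and lower for Kif11 (at least 2.29-fold). Of 8 histone genes H2ax and H2aj rose, by 2.04 ± 0.32 and 1.44 ± 0.31 (list median 0.51, 3 higher adjusted over the list alone). For the list camera gave adjusted p = 0.0515 with the preset and 0.36 with an estimated correlation, and fry gave adjusted p = 0.00154. The 31 proteasome genes had 4 that rose and 1 that fell (7 and 1 adjusted over the list alone; median 0.32, camera adjusted p = 0.337). Psmd12, Psmd6 and Psmb6 rose by 1.47 ± 0.36, 1.10 ± 0.22 and 0.99 ± 0.19, and Psmc1 changed by -1.96 ± 0.39.

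Few genes of mRNA decay apart from the targets passed the test by their brightest probe set. Small changes can be missed, as the simulation recovered 28 of 100 changes of 2-fold. Fewer probe sets were changed there than were called in the data, so adjustment was stricter and this share may be too low. In the list of 20 decapping and 5′-to-3′ decay genes only Dcp1a and Dcp2 passed the test, and none of 21 deadenylation genes did by that probe set, either overall or adjusted over the list alone (camera adjusted p = 0.374 for the decapping list and 0.929 for deadenylation). The mixed test of fry, which counts changes in either direction, gave adjusted p = 0.0349 for deadenylation and 0.00814 for the list of exosome and nonsense-mediated decay, and it passed for 15 lists that camera had not called. Nearest among these probe sets of the deadenylation list were Tnrc6c, at 0.78 ± 0.23, and Tnrc6a, at -1.36 ± 0.43 (log2, SE; adjusted p = 0.0662 and 0.0764, limma). Another probe set of Tnrc6a was called lower (at least 1.18-fold, adjusted p = 0.0163) and 1 of Tob2 higher (1.95 ± 0.48, adjusted p = 0.0302), both chosen after their values were seen. Of 18 exosome and nonsense-mediated decay genes the cytoplasmic exonuclease Dis3l rose by 2.05 ± 0.36 (list adjusted p = 0.73). Of 27 translation control genes the germ cell mRNA-binding protein Ybx2 rose by 1.76 ± 0.41 (list adjusted p = 0.631). None of 14 small RNA genes passed by the same probe set, with Drosha nearest at 1.23 ± 0.34 (adjusted p = 0.0503, limma). Of the 28 dormant maternal mRNAs recruited at maturation only Dcp1a and Dcp2, which belong to that list, passed by that probe set (median -0.03). Other probe sets, chosen after their values were seen, were called lower for Ttc37 and Hbs1l of the exosome and nonsense-mediated decay list, Elavl2 of translation control, Asz1 of the small RNA list and Kif11 of the dormant mRNAs, and higher for Dicer1 (1.40 ± 0.36).

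Other lists held few genes called by the brightest probe set, and further ones were called only by another, 4 in the chromatin list, 2 in the p53 and stress list, and 1 each in splicing and zygotic genome activation. In 38 splicing genes Srsf10 fell (-1.75 ± 0.36), and in 37 chromatin genes Zfp57 rose and Suv39h2, a histone H3 lysine methyltransferase, fell (-0.84 ± 0.21). Arg2 rose by 2.32 ± 0.52 among 10 genes of zygotic genome activation. Ddit3, a transcription factor of the unfolded protein response, and the chaperone gene Hspa8 rose by 1.90 ± 0.29 and 1.36 ± 0.26 among 22 genes of the p53, apoptosis and stress list. None of 8 interferon or double-stranded RNA response genes and none of 6 immediate-early genes passed (limma). Camera adjusted p-values of these 6 lists were between 0.3 and 0.929. Of 28 cumulus and granulosa cell markers only 2 passed the filter on low values, Nr5a2 and Kitl, and these had fitted changes of -0.38 ± 0.20 and -0.49 ± 0.33. A single marker of other ovarian, stromal or blood cells was tested, Kdr, with a change of -0.37 ± 0.16. Neither marker list passed camera (adjusted p = 0.375 and 0.399), and fry called both lower (adjusted p = 0.0359 and 0.0429).

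A large single rise in the double knockdown was that of the ribosomal RNA processing factor gene Fcf1 (3.92 ± 0.28, log2, SE, limma). Other genes had a mean or median at or below log2 5 in control eggs, so only bounds can be given. These bounds allow for the floor and not for the spread among arrays. Control SDs on the log2 scale ran from 0 for Znrd2 to 1.681 for Ppil3, 2.245 for Pum3 and 2.329 for Eif4h. The translation initiation factor gene Eif4h was at least 15.3-fold higher (adjusted p = 0.0152, limma). Ppil3, a cyclophilin-like protein, was at least 10.2-fold higher (adjusted p = 0.000931, limma), the Pumilio-family gene Pum3 at least 5.66-fold and Nelfe, a subunit of the negative elongation factor, at least 10.5-fold. The only other probe set of Pum3 was not called (0.14). Trdn was at least 6.74-fold higher, the membrane transport gene Yif1a at least 4.53-fold, Znrd2 at least 2.35-fold and the COP9 signalosome gene Cops6 at least 1.83-fold (adjusted p of 0.0145, 0.000825, 1.72e-05 and 5.76e-06, limma). Large falls besides the targets were those of Edrf1 (-2.79 ± 0.37, adjusted p = 0.00125), the microtubule depolymerase gene Kif2a (-2.58 ± 0.49, adjusted p = 0.00819), Vps41 (-2.57 ± 0.53) and nucleolin, Ncl (-2.40 ± 0.42, adjusted p = 0.00535). Nap1l3, Rps6ka5, Gtf2f2, Rnf17 and Brwd3 had changes between -2.36 and -2.11, and Zfp445 was at least 1.65-fold lower. For Vps41 the other probe set, for Ncl both others and for Edrf1 1 of 2 others changed upward. The other probe sets of Kif2a, Rps6ka5, Zfp445, Rnf17 and Brwd3 changed downward and were not called. Ncl and Ltn1 each had probe sets called in both directions. Each gene named for a large fall also had a lower mean in the Dcp2 knockdown than in control eggs. Besides Dcp2 none of them was called there, and none had a downward departure from additivity. Mean log2 values in control, Dcp2 knockdown and double knockdown were 9.11, 6.95 and 6.32 for Edrf1. They were 8.92, 6.93 and 6.35 for Kif2a and 8.67, 7.35 and 6.10 for Vps41.

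**Figure D3:**
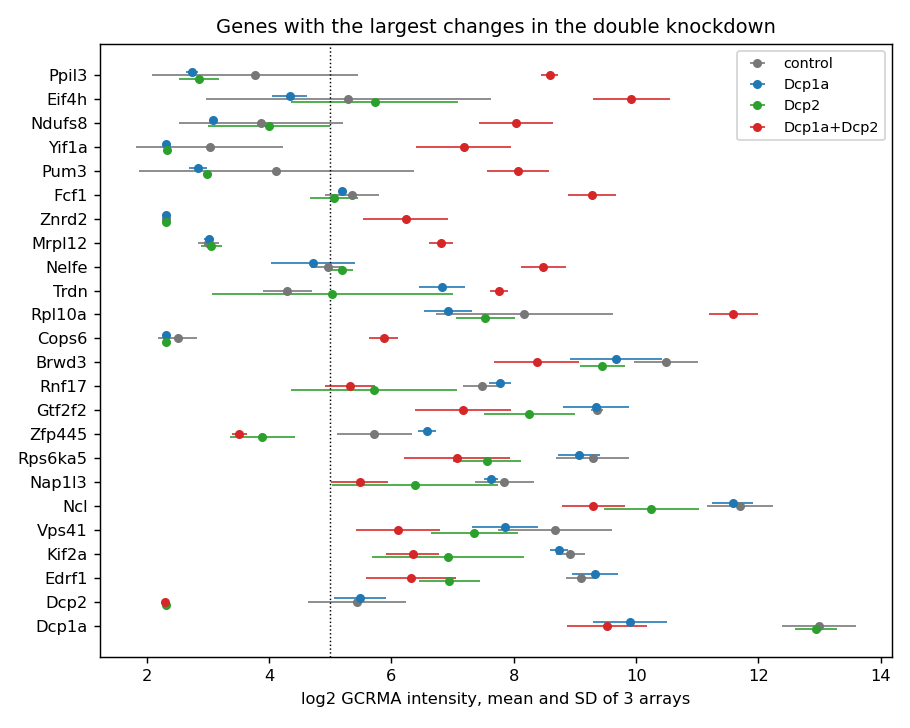
Log2 GCRMA intensity (mean and SD of 3 arrays per group) of genes with large changes in the double knockdown, by siRNA injected, with a dotted line at log2 5, the filter level. Ppil3 was at least 10.2-fold higher in the double knockdown than in control eggs, and Edrf1, Kif2a and Ncl were lower there than in control eggs.

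The number of calls depended on single arrays and on the setting. It was 2451 without control replicate 1, 460 without control replicate 2, 534 without double knockdown replicate 1 and 444 without double knockdown replicate 2, and 277 with the variance taken from the 6 arrays compared. Of 52 named genes past the threshold, 20 lost the call without control replicate 2, 17 without double knockdown replicate 1 and 23 without double knockdown replicate 2, with adjusted p up to 0.131 (limma). The calls were split 699 higher to 364 lower under median centring and 733 to 404 under quantile normalization and 740 to 444 without double knockdown replicate 3, against 768 to 243 as deposited.

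Whether the combined effect was larger than the sum of the single effects was tested as an interaction on the log2 scale. In 456 probe sets the double knockdown departed from additivity, 452 of them upward and 4 downward (limma, Benjamini-Hochberg adjusted p under 0.05). The split was 546 to 80 without control replicate 1, and 1137 to 205 at an unadjusted p under 0.05. The same 3 lists led, with upward departures in 13 of 40 ribosomal protein genes, 20 of 67 oxidative phosphorylation genes and 10 of 56 mitochondrial ribosomal protein genes, and downward ones in 0 of each. Adjusted over the list alone the numbers were 21, 26 and 10. Median log2 departures were 1.26, 0.75 and 0.27. Camera adjusted p-values were 5.23e-19, 8.26e-18 and 2.46e-06 with the preset correlation, and 0.0642, 0.0853 and 0.0853 with an estimated correlation. The proteasome list also passed with the preset (adjusted p = 0.036), with 3 of 31 genes upward, and had adjusted p = 0.385 with an estimated correlation. Large upward departures were those of Ppil3 (6.76 ± 0.87), Pum3 (6.37 ± 1.15), the vacuolar proton pump subunit Atp6v1d (5.81 ± 1.02), Yif1a (5.56 ± 0.73) and Rps4x (5.41 ± 0.98, log2, SE, limma). Several of these lay near the floor in the single knockdowns, so these sizes are fitted values and not folds. The only other probe set of Pum3 departed in the opposite direction (-0.32). The downward ones were Syne1 (-1.38 ± 0.25), the kinase gene Stk36 (-1.29 ± 0.28), the histone chaperone gene Hira (-0.91 ± 0.21) and the predicted gene Gm10512 (-1.55 ± 0.38), the last chosen after its values were seen. The number of departures fell to 274, 264 and 252 without Dcp1a knockdown replicates 1, 2 and 3, and to 280 and 275 without double knockdown replicates 1 and 2. It was 217 without both Dcp2 knockdown replicates 1 and 3, which leaves 1 array in that group and takes the spread from the others.

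At an unadjusted p under 0.05 Dcp1a siRNA alone gave 570 probe sets, near the 0.05 share of the 11593 tested that no effect would give. After adjustment it changed 6 probe sets, 2 upward and 4 downward (limma, Benjamini-Hochberg adjusted p under 0.05). Besides Dcp1a itself these were Uba6, a ubiquitin-activating enzyme, at least 1.78-fold higher, and Syne1, a nuclear envelope protein, at least 1.58-fold higher. The sorting nexin gene Snx6 fell (-2.19 ± 0.31, adjusted p = 0.0445) and so did Pdk1, an inhibitor of the pyruvate dehydrogenase complex (-1.70 ± 0.21, adjusted p = 0.0291, limma). The other probe sets of Snx6 (-0.19) and Pdk1 (-1.61) were not called. Mean log2 values in control, Dcp1a knockdown and double knockdown were 7.59, 5.40 and 8.17 for Snx6 and 12.06, 10.36 and 11.61 for Pdk1. They were 4.34, 5.66 and 4.35 for Syne1 and 2.29, 5.83 and 4.67 for Uba6. With both siRNAs Snx6, Pdk1 and Syne1 thus lay nearer to control than to the Dcp1a knockdown. No member of the ribosomal protein, mitochondrial ribosomal or oxidative phosphorylation lists changed, with list medians of -0.20, -0.06 and -0.16. Camera called these lists lower with the preset correlation (adjusted p = 0.000719, 0.00542 and 0.00029), and gave adjusted p = 0.595 for each with an estimated correlation. The count was 372 without control replicate 1, and 1 without any of control replicates 2 and 3, the 3 Dcp1a knockdown replicates or double knockdown replicate 1. It was 2 without Dcp2 knockdown replicate 1 and 3 without double knockdown replicate 3.

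At an unadjusted p under 0.05 Dcp2 siRNA alone gave 1283 probe sets, 356 higher and 927 lower than in control eggs (limma). After adjustment it changed 2, both downward. They were Dcp2 and the zinc finger gene Rlf, which was at least 2.43-fold lower (adjusted p = 0.0152, limma, for both). No list passed camera. The count was 223 without control replicate 1 and 12 without Dcp2 knockdown replicate 2. It was 1 without control replicate 3, and 0 without Dcp1a knockdown replicate 2, Dcp2 knockdown replicate 1 or 3, or double knockdown replicate 1.

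The double knockdown was also compared with each single one. Against the Dcp1a knockdown 959 probe sets were higher and 439 lower, and against the Dcp2 knockdown 710 were higher and 29 lower (limma, Benjamini-Hochberg). Ppil3 was at least 12-fold higher than in either single knockdown, Pum3 at least 8.40-fold and Yif1a at least 4.53-fold. The other probe set of Pum3 changed by 0.21 against the Dcp1a knockdown and -0.39 against the Dcp2 knockdown. Eif4h was at least 30.3-fold and Ndufs8 at least 8.24-fold higher than in the Dcp1a knockdown, and Rps4x and Fcf1 rose by 4.54 ± 0.69 and 4.22 ± 0.28 against the Dcp2 knockdown (log2, SE). Against the Dcp1a knockdown Edrf1 changed by -3.01 ± 0.37 and the laminin gene Lamb1 by -2.58 ± 0.47, and Dcp2, Zfp445 and Zfyve16 were at least 1.41-fold, 3.01-fold and 3.24-fold lower. Against the Dcp2 knockdown the largest falls were Dcp1a (-3.42 ± 0.42), the centriole gene Cep164 (-2.45 ± 0.61), Car10 (-1.62 ± 0.33), Stk36 (-1.49 ± 0.20) and Tfpi (-1.35 ± 0.32). For Lamb1 1 of 2 other probe sets, for Edrf1 1 of 2 and for Cep164 the only other changed upward. Ribosomal protein genes numbered 22 of 40 higher and 0 lower against Dcp1a knockdown, and 19 higher and 0 lower against Dcp2 knockdown, with list medians of 1.26 and 1.12. Camera adjusted p-values were 1.41e-14 and 1.85e-16 with the preset, and 0.135 and 0.0969 with an estimated correlation.

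Of the 768 probe sets higher than in control eggs, 649 were also higher than in the Dcp1a knockdown and 554 than in the Dcp2 knockdown. Independent lists of these lengths would share 63.5 and 47.0, values that leave out the shared double knockdown arrays. Part of the overlap may come from those arrays. Against all 3 other groups 531 probe sets were higher, and 376 of these also had an upward departure from additivity. Of the 243 lower probe sets 175 were also lower than in the Dcp1a knockdown and 20 than in the Dcp2 knockdown. The count against the Dcp1a knockdown, 1398 in all, was 811, 774 and 727 without Dcp1a knockdown replicates 1, 2 and 3, 793 and 702 without double knockdown replicates 1 and 2, 2298 without double knockdown replicate 3 and 2162 without Dcp2 knockdown replicate 2. The excess of higher over lower calls against the Dcp1a knockdown did not hold in every setting. The calls were split 1066 higher to 1096 lower without Dcp2 knockdown replicate 2 and 1007 to 1291 without double knockdown replicate 3. With only the arrays of both groups the excess remained but was smaller in proportion, at 1488 to 1291. At an unadjusted p under 0.05 there were 1552 higher and 2129 lower. The count against the Dcp2 knockdown, 739 in all, was 471 and 477 without double knockdown replicates 1 and 2.

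**Figure D4:**
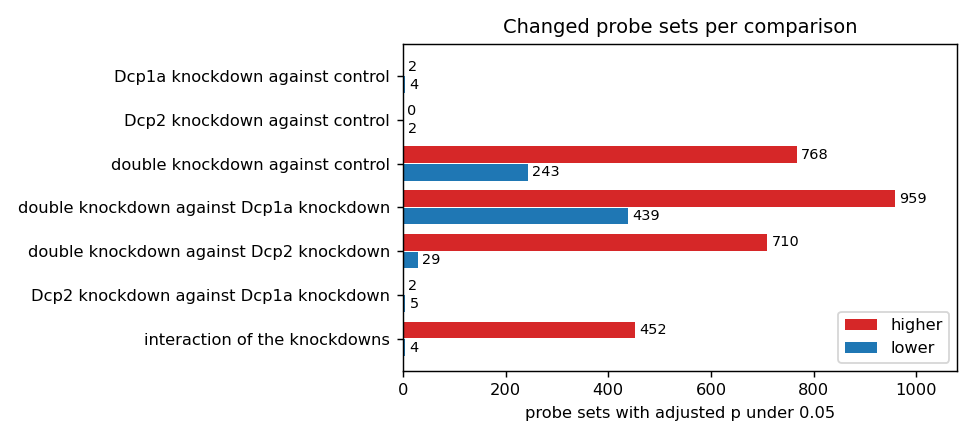
Number of probe sets with an adjusted p under 0.05 (limma) in each of the 7 comparisons, higher in red and lower in blue. The bars for the double knockdown reach 959 higher against the Dcp1a knockdown, while the single knockdowns against control reach 2 higher and 4 lower.

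The single knockdowns differed from each other in 7 probe sets, 2 higher and 5 lower after Dcp2 siRNA, against 2564 at an unadjusted p under 0.05 (limma, Benjamini-Hochberg). Both higher probe sets belonged to Dcp1a (3.04 ± 0.42, log2, SE, for the brighter). The lower ones were Uba6, Dcp2, Zfp445, Rlf and Syne1, by at least 1.78-fold, 1.41-fold, 3.01-fold, 2.36-fold and 1.58-fold. The count was 1866 without Dcp2 knockdown replicate 2, 0 without Dcp1a knockdown replicate 2 or 3, and 1 without Dcp1a knockdown replicate 1 or Dcp2 knockdown replicate 1 or 3. Under median centring it was 3 higher and 2 lower, under quantile normalization 2 and 1, and under cyclic loess 3 and 4.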

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

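The tests of cumulus cell carry-over, array scale, Dcp2 and Dcp1a levels and control noise were chosen after the results were seen. Those of floor compression, hybridisation strength and other splits of the arrays were set before. In 456 probe sets the change in the double knockdown departed from the sum of the single changes (limma interaction, Benjamini-Hochberg). Gene lists departed too, with median log2 departures of 1.262 for ribosomal proteins, 0.2709 for mitochondrial ribosomal proteins, 0.7479 for oxidative phosphorylation and 0.3767 for histones (fry, adjusted p under 0.05). Camera gave adjusted p = 0.0731 for histones with the preset correlation and 0.253 with an estimated one, and with an estimated one 0.0642, 0.0853 and 0.0853 for the other 3 lists. Among array controls outside the comparisons, the 3′ Gapdh probe set was 1.292 higher on the log2 scale in the double knockdown than in control, and the middle Gapdh probe set 1.57 higher. Array controls were listed here only where all 3 arrays of a knockdown lay above all 3 control arrays. The exact permutation p of 0.1, the smallest possible, thus followed from that choice and is no test of it. The difference between the 3′ and middle Gapdh probe sets was -0.28 (exact p = 0.4, where 0.1 is the smallest possible).

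The first pattern is the rise of ribosomal and oxidative phosphorylation transcripts in the double knockdown. Carry-over of cumulus cells is argued against by 0 of 28 cumulus markers being above the filter level and at least 1 log2 unit higher there. Scale differences between arrays are argued against by 1043 changed probe sets under cyclic loess, near the 1011 as deposited. Compression of dim values near the floor stays open. The 87 members with a mean above log2 8 had a median change of 0.2711 (resampling SE 0.0805), 17 of them called higher and 1 lower. This median met the limit set beforehand for compression, which asked for no error. The SE resampled genes measured on the same arrays, so it is not an error over replicates and cannot decide the question. Medians of the whole lists, taken for each list and not pooled as for the 87 members, were 1.20 for ribosomal proteins, 0.57 for oxidative phosphorylation and 0.28 for mitochondrial ribosomal proteins. Of the 10 splits of the 6 arrays, 1 (the real one) reached 1011 and the highest other gave 0, too few splits for a share under 0.05. A lower decay of these stored mRNAs without both decapping factors is a biological hypothesis from the design, which these relative values do not test against a change in total mRNA.

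The second pattern is the excess over additivity. Noise of the control arrays, which enter the interaction, stays open. Without 1 of them the lowest count was 408 and the highest 626, so the departures did not rest on a single control array. The remaining controls stay in each such fit. Genes named for large upward departures had control SDs from 1.203 (Yif1a) to 2.245 (Pum3) on the log2 scale. Of 100 random assignments of the 12 arrays to the 4 groups, the real one included, 2 gave as many departures (456, highest other 689). The share was under the 0.05 set beforehand, but random assignment removes every difference between groups, not only a departure from additivity. Chance as a source of the excess is therefore not excluded. Which arrays the assignment with 689 exchanged was not examined, so its relation to the labels is unknown. A redundant or joint action of both factors is a hypothesis that may account for the excess; with a log2 scale, a floor on the single knockdowns would also add to it. The 217 departures left without Dcp2 knockdown replicates 1 and 3 rest on 1 array of that group, with the spread taken from the other groups, and do not decide this.

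The third pattern is the spread among Dcp2 knockdown arrays, where replicate 2 stood apart from replicates 1 and 3. Incomplete knockdown in 1 array stays open, since the highest Dcp2 intensity of 5 in the 3 arrays lies at the floor, where degrees of depletion cannot be told apart. An exchange of labels with the double knockdown is argued against by a lowest Dcp1a intensity of 6397.2 in the Dcp2 knockdown arrays against a highest of 1233.3 in the double knockdown. An exchange with a control array is argued against by the Dcp2 readings, which were 30.4 to 81.8 in the 6 arrays without Dcp2 siRNA (32.2 in control replicate 1) and 4.9 to 5 in the 6 arrays with it (exact rank-sum p = 0.00216). The strength of hybridisation stays open: over the 9 other arrays, centred within groups, the level of hybridisation controls correlated with the position on this axis at Pearson's r = 0.625 (permutation p = 0.0736) and Spearman's rho = 0.433 (permutation p = 0.248), and r was 0.443 without the 2 farthest arrays. In the Dcp2 knockdown against control, 3 of 10 splits gave as many calls as the real 2, and the split that exchanged control replicate 1 with Dcp2 knockdown replicate 2 gave 1305, which points to a structure of the samples that the labels do not name.

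For the other comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real split was the 1 with the most calls for the Dcp1a knockdown against control (6, highest other 2), the double against the Dcp1a knockdown (1398, highest other 0), the double against the Dcp2 knockdown (739, highest other 1) and the Dcp2 against the Dcp1a knockdown (7, highest other 0).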

How the results depend on the processing

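Setting values under 32 to 32 and leaving out Dcp2 knockdown replicates 1 and 3 together were chosen after the data were seen. No named gene or siRNA target past the threshold changed sign under any alternative run, but the balance of higher and lower calls turned in some, as given below. Counts are given in the order Dcp1a, Dcp2 and double knockdown against control, double against Dcp1a, double against Dcp2, Dcp2 against Dcp1a knockdown, and interaction, with values as deposited giving 6, 2, 1011, 1398, 739, 7 and 456. The cause of a difference was not tested unless stated.

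Replicate numbers did not pair the samples: 9 of 18 same-number pairs had residual correlations over 0.1 (range -0.685 to 0.394), and 3 of 12 arrays correlated best with their own number. With the replicate block the counts were 1, 2, 819, 1091, 615, 1 and 331, and Dcp1a in its own knockdown stayed at -3.09 with adjusted p = 0.176 (limma).

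Without the filter, which puts over 3 times as many probe sets under adjustment, counts were 1, 2, 527, 842, 489, 3 and 160. The 1, the 2 (both higher, against 2 lower with the filter) and the 3 shared 0 calls with the values as deposited and filtered. With a filter at log2 7, which tests fewer, they were 2, 0, 627, 894, 426, 0 and 271. With only the arrays of the 2 groups, which leaves fewer residual degrees of freedom, they were 2, 0, 277 and 2779, and 2 for Dcp2 against Dcp1a knockdown. With array weights they were 1, 1752, 4643, 8046, 6563, 6524 and 1385, but the weight estimate stopped before it converged and gave double knockdown replicate 1 a weight of 56.1, so these counts are not reliable. They were split 3189 higher to 4857 lower for double against Dcp1a knockdown. With 16 added to each intensity the counts that moved were 3, 0 and 0 (Dcp1a and Dcp2 against control, Dcp2 against Dcp1a knockdown), and with values under 32 set to 32 the same 3 were 0, 0 and 0. Dcp2 against control gave 1 under median centring and 1 under quantile normalization, and Dcp2 against Dcp1a knockdown gave 3 under quantile normalization. The interaction gave 292 without probe sets that can match several transcripts and 217 without Dcp2 knockdown replicates 1 and 3, which leaves 1 array in that group. Other scalings moved the median of all probe sets by over 0.1, as for Dcp2 against control, from -0.11 to 0.07 under median centring.

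For Dcp1a in its own knockdown the call was also lost without the filter (-3.09, adjusted p = 0.402), with array weights (-2.99, 0.115), with values under 32 set to 32 (-3.09, 0.0801) and with only 2 groups (-3.09, 0.472). For Dcp2 in its own knockdown it was lost without the filter (-3.12, 0.161), with 16 added (-1.52, 0.196), with values under 32 set to 32 (-0.45, 0.508) and with only 2 groups (-3.12, 0.691). In the double knockdown Dcp2 lost it with values under 32 set to 32 (-0.45, 0.38). Dcp2 lay near 32 in control eggs, so its log2 values here and below are fitted against the floor and neither measure nor bound its change, for which only at least 1.35-fold can be given.

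Leaving out 1 array at a time, counts ranged from 1 to 372, 0 to 223, 444 to 2451, 702 to 2298, 471 to 863, 0 to 1866, and 252 to 626. Without Dcp2 knockdown replicate 2 the double against Dcp1a knockdown had 1066 higher and 1096 lower, and without double knockdown replicate 3 it had 1007 and 1291. Without control replicate 1 the calls against control were 331 higher and 41 lower for Dcp1a knockdown, and 188 and 35 for Dcp2 knockdown. Fitted log2 changes ranged from -3.39 to -2.74 for Dcp1a and from -3.37 to -2.66 for Dcp2 in their own knockdowns, and from -3.84 to -3.17 and -3.38 to -2.67 in the double knockdown. Of 87 results on named genes past the threshold, 55 lost the call in at least 1 setting. The 3 lists past camera in the double knockdown lost it with an estimated correlation.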

Other observations

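Grouping genes by the root of their symbol, a grouping chosen after the data were seen, added little to the lists. In the double knockdown against control, higher calls were made for 8 of 19 genes of the Rpl family, 8 of 21 of Rps, 9 of 33 of Mrpl and 5 of 11 of the complex I family Ndufa. These counts restate the lists of ribosomal, mitochondrial ribosomal and oxidative phosphorylation genes, whose camera adjusted p was 0.289, 0.36 and 0.36 with an estimated correlation.

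The change brought by Dcp2 siRNA could be compared in arrays that share none, as Dcp2 knockdown minus control and as double minus Dcp1a knockdown. Across 6998 genes, which are not independent replicates, these correlated at r = 0.431 (rho = 0.58), consistent with a response to Dcp2 siRNA shared by both backgrounds. The same comparison for Dcp1a siRNA gave r = -0.103 (rho = 0.113). The correlation rested on Dcp2 knockdown replicates 1 and 3, with r of 0.475 and 0.468 for each array against the mean control, while replicate 2 gave -0.117. An axis of variation shared with control arrays stays open. Control replicate 1 minus the other 2 gave r = 0.0611, under the 0.1 set against it beforehand, but control replicates 2 and 3 gave -0.23 and 0.123 in the same way. The sign of an axis is arbitrary, so a limit on replicate 1 alone was too narrow. The Dcp2 and double knockdowns, both set against the same controls, correlated at 0.57, where simulated unchanged groups gave 0.499. The covariance was 0.217 against a simulated 0.0636. For the Dcp1a and double knockdowns r was 0.0598 against 0.5, and the covariance 0.0164 against 0.0637. For the Dcp1a and Dcp2 knockdowns r was 0.223 against 0.498, and the covariance 0.0398 against 0.0636. The simulation gave a gene the same SD in all groups and let genes vary independently. In the data the median SD ran from 0.159 in the Dcp1a to 0.376 in the Dcp2 knockdown, so the simulated values are only a rough reference.

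A fall in the double knockdown may concern 1 part of a transcript and not the gene. Of 257 other tested probe sets of the genes that fell, which were not called themselves, 73.5% also changed downward (exact binomial interval 67.7% to 78.8%). The limits set beforehand, 75% for the whole gene and 60% against it, were for all other tested probe sets. Leaving out the called ones can lower the share, so it does not decide between these limits. Of 232 such probe sets of the genes that rose, 63.8% changed upward, a share that the same omission can lower.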
